A study of Mus musculus with 24 samples.

How the data were processed

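Total RNA of infarcted heart tissue from male C57BL6/J mice was measured on 24 one-colour Agilent SurePrint G3 Mouse GE 8x60K arrays, 1 array per sample and 4 arrays in each of 6 groups. Per the labels, the tissue was the area at risk of the anterior wall, taken 24, 48 or 168 h after the left anterior descending artery, closed for 45 min, was reopened. The IGF1 groups received 40 ng/g of recombinant insulin-like growth factor 1 under the skin when reperfusion began and then 1 µg/g per day from an implanted pump for up to the first 3 days, and the vehicle groups received carrier solution. The labels of every vehicle sample name 45 min of ischemia, whereas the series design text speaks of sham-operated controls. The sample labels were followed, so IGF1 against vehicle is read here as treatment after infarction.

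Each array's deposited scanner output was written by Agilent Feature Extraction 12.0.3.2, per the file headers, from arrays labelled with Cy3. The processed signal in it is an intensity on a linear scale that Feature Extraction had corrected for background within the array and that had not been scaled between arrays, per the file headers. The value table the authors deposited holds log2 values of 33957 probes, of which 23 are control probes and 0 are missing from the scanner output. Set against the log2 values computed here, each of its probes differed by 1 offset common to all arrays, with a residual SD of at most 2.19e-06 and a correlation of 1, so the authors' log2 values lie on the same scale after centring each probe. Its column medians lay between -0.0557 and 0.0527. Which arrays the centring used and how its probes were chosen are not given in the sources used here.

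From the scanner output, control spots and spots marked as non-uniform or population outliers were left out, which took 53 to 130 of the 59305 spots of an array, and 0 spots were saturated. Log2 of the processed signal minus the 75th percentile of the array (534 to 897 before log2) was the measure, and spots of one probe were averaged. A probe was kept if it was well above background on at least 4 of the 24 arrays, and the brightest kept probe stood for its gene. Symbols came from the accessions on the array, matched without version numbers to the reference table of mouse RefSeq genes: 33767 of 56605 probes (59.7%) had 1 symbol, 22838 had none here and 0 had several. That left 15875 genes, of which 5924 had several kept probes and 24 lacked a value on an array. The number of arrays, 4 per group, limits the precision.

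Groups were compared with limma 3.58.1 in R 4.3.3: lmFit with 1 mean per group over all 24 arrays, which leaves 18 residual degrees of freedom, and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. Adjusted p-values of single genes come from this fit. The comparisons were IGF1 against vehicle at each time, the mean of these 3 differences, the F-test of whether the IGF1 effect differs between times, and 48 h against 24 h and 168 h against 48 h in each treatment. Errors of log2 differences are standard errors (SE) of the fit and errors of group means are SD over 4 arrays. A gene that was well above background on 0 arrays of one group has only a bound, written "at least N-fold": the brighter group's mean against the dimmer group's mean of, per array, the lowest signal among probes well above background or the probe's own signal where that was higher. Where only some arrays of a group measured a gene, their number is given.

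The groups, comparisons, tests, alternatives, 33 gene lists (16 of cell types or other tissues, 17 of processes) and the rule for naming genes were fixed before the data were examined. Of the 518 list genes, 491 were measured. A list was called by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 33 lists of a comparison. Camera with an estimated correlation stands beside it. Limma's fry, which asks whether a list's genes move 1 way on balance and does not compare them with other genes, called 10, 3 and 0 lists at 24, 48 and 168 h, 4 in the mean over times, 12 and 26 in vehicle hearts and 17 and 21 in IGF1 hearts. The naming rule took up to 10 higher and 10 lower genes with the largest changes among those past the threshold whose 2 groups of arrays did not overlap (for the mean over times, those with the same sign at all 3 times), leaving out clone, predicted and accession-only names; the 10 smallest p-values of the F-test; up to 4 members of each list with the smallest p; 5 higher and 5 lower genes with the smallest p where fewer than 5 passed; and 25 genes named in advance, of which 24 were measured (Il10 was not). The text gives a part of these, and which part was chosen after the values were seen. Some of the genes so selected are not reported here.

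Alternatives were normexp background correction with an offset of 50 (on the median signal, the raw foreground column of the files used here) and the local background median, quantile normalization, no filter on dim probes, a filter for well above background on all 24 arrays, the mean of a gene's probes, the authors' value table, slide as a fixed block (meant where not stated) and as a random block, the replicate number as a block, array weights, only the groups compared, and leaving out each array in turn. For lists under the random slide block, camera's preranked form was run on the moderated statistics. The arrays lay on 4 slides read on 2 scan days. Slides holding both treatments numbered 4 at 24 h, with 1 array of each, and 2 at 48 h and at 168 h. At 24 and 168 h both treatments were spread over the slides alike, so a slide block cannot move their differences. List means per array use members with a value on all arrays.

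Whether equal replicate numbers pair arrays was checked from the correlation of their deviations from the group means. At 168 h, IGF1 and vehicle arrays of the same number correlated with r of 0.186 to 0.502 (mean of other pairs -0.097), and 4 of 4 IGF1 arrays correlated best with the vehicle array of their own number. The labels do not say what the number marks, so this pairing comes from the data. A fit of the 168 h arrays alone with the replicate number as a block was therefore added after seeing the data.

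The steps were tested on simulated data. Over 15851 genes with 100 changed by log2 0.5 and 100 by log2 1 between the 24 h groups, 41 and 76 were recovered with 7 false calls. With the 20 contractile genes shifted by log2 0.5 between the 48 h groups, that list alone was called. Splits of the real 48 h arrays called up to 13, so false list calls were not gauged. In each of 5 unchanged comparisons 0 genes were called.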

Results

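Gene expression was measured in the infarct tissue of mouse hearts after 45 min of coronary occlusion and 24, 48 or 168 h of reperfusion. Mice had received either insulin-like growth factor 1 (IGF1), a hormone that promotes cell growth and survival, or vehicle, and each of the 6 combinations of treatment and time was represented by 4 arrays. The array reports messenger RNA as fluorescence of gene-specific probes, given as log2 signal relative to the 75th percentile of the array. Between 52.8 and 62.9% of the spots of an array were well above background, and 15875 genes were tested. Arrays of the same group correlated with r of 0.983 to 0.993 across genes, and genes are not independent replicates. The labels call the arrays separate samples without naming the animals, so p-values measure the spread between these samples.

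The comparison of IGF1 with vehicle at each time asks how the treatment changed expression in the area at risk. At 24 h, genes that break down fatty acids were higher with IGF1. Of 21 measured fatty acid oxidation genes, 19 rose and 0 fell, with 19 higher adjusted over the list alone. The median log2 difference was 0.75 (camera adjusted p = 2.05e-14, adjusted p = 0.226 with estimated correlation). Cd36, which carries fatty acids into the cell, was 1.99-fold higher (log2 0.99, SE 0.15, adjusted p = 0.000632). It stood at 5.15 ± 0.22 with IGF1 and 4.16 ± 0.22 with vehicle (SD, n = 4). Cpt1b, which admits fatty acids to the mitochondria of muscle, was 2.04-fold higher (adjusted p = 0.00193). Mlycd, which removes the inhibitor malonyl-CoA, was 2.11-fold higher (adjusted p = 0.00107), and the thioesterase Acot2 was 2.61-fold higher (adjusted p = 0.00127). Pdk4, a kinase that shuts down pyruvate dehydrogenase and so spares glucose, was 3.58-fold higher (log2 1.84, SE 0.33, adjusted p = 0.00198). Pdk4 belongs also to the list of FoxO target genes, 22 of which were measured. Of these 6 rose and 0 fell (7 higher adjusted over the list alone). Their median was 0.30 (camera adjusted p = 0.00492, adjusted p = 0.472 with estimated correlation). Among them were the muscle ubiquitin ligase Fbxo32, 2.19-fold higher (adjusted p = 0.00429), and the mitophagy receptor Bnip3, 1.90-fold higher (adjusted p = 0.00314).

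Of 21 genes of oxidative phosphorylation and the tricarboxylic acid cycle, 18 rose and 0 fell, with 21 higher adjusted over the list alone. The median was 0.43 (camera adjusted p = 4.3e-10, adjusted p = 0.472 with estimated correlation). The cycle enzyme gene Ogdh was 1.46-fold higher (adjusted p = 0.00755). Of 20 genes of the cardiomyocyte contractile apparatus, 7 rose and 1 fell, with 8 higher and 1 lower adjusted over the list alone. The median of that list was 0.30 (camera adjusted p = 0.000283, adjusted p = 0.536 with estimated correlation). Atp2a2, the calcium pump of the sarcoplasmic reticulum, was 1.72-fold higher (log2 0.78, SE 0.16, adjusted p = 0.00401), and the Z-disc gene Myoz2 was 1.67-fold higher (adjusted p = 0.00248). The member that fell, the Z-disc protein gene Csrp3 (log2 -0.34, adjusted p = 0.0465), lost its call under 4 other settings and without 6 of the 8 arrays in turn (0.0255 to 0.151 over all alternatives). Within the 4 slides, which each held 1 array of either treatment, the mean of the fatty acid oxidation list was higher with IGF1 on 4 of 4, by 0.57 to 1.11. The oxidative phosphorylation list was higher by 0.22 to 0.57, the FoxO list by 0.20 to 0.53 and the contractile list by 0.04 to 0.51, each on 4 of 4 slides. IGF1 replicate 1 stood apart in the oxidative phosphorylation list (mean 7.69, other IGF1 arrays 7.35 to 7.36).

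Genes of antigen presentation and of lymphocytes were lower with IGF1 at 24 h. In the list of dendritic cell and MHC class II genes, 13 of 15 fell and 0 rose, with 13 lower adjusted over the list alone. The median was -1.10 (camera adjusted p = 3.06e-10, adjusted p = 0.226 with estimated correlation). Ciita, the master activator of class II genes, was 2.73-fold lower (log2 -1.45, SE 0.26, adjusted p = 0.00199). The class II beta chain H2-Ab1 was 2.29-fold lower (adjusted p = 0.00335), and Flt3, the receptor that drives dendritic cell development, was 2.38-fold lower (adjusted p = 0.0019). Of 13 T and NK cell markers, 8 fell and 1 rose, with 10 lower and 1 higher adjusted over the list alone. The median was -0.92 (camera adjusted p = 2.06e-05, adjusted p = 0.226 with estimated correlation). The NK cell receptor gene Klrd1 was 3.46-fold lower (log2 -1.79, SE 0.22, adjusted p = 0.000299), and the T cell receptor kinases Lck and Zap70 were 1.91-fold and 2.20-fold lower (adjusted p = 0.00164 and 0.00487). The member that rose was the costimulatory receptor Cd28 (log2 0.53, adjusted p = 0.0258). Its call was lost without vehicle replicate 2 (0.0722), vehicle replicate 3 (0.0577) or IGF1 replicate 1 (0.108), with a range of 0.0146 to 0.108 over all alternatives. Of 7 B cell markers, 4 fell and 0 rose (4 lower adjusted over the list alone). The median was -1.12 (camera adjusted p = 0.00266, adjusted p = 0.226 with estimated correlation). Cd79b was 2.27-fold lower and Ms4a1, which codes for CD20, 3.51-fold lower (adjusted p = 0.00349 and 0.00142), and 3 of 4 IGF1 arrays had Ms4a1 above background. The means of the class II, T and NK cell and B cell lists were lower with IGF1 on 4 of 4 slides, by -1.26 to -0.70, -1.15 to -0.53 and -1.01 to -0.55.

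**Figure D1:**
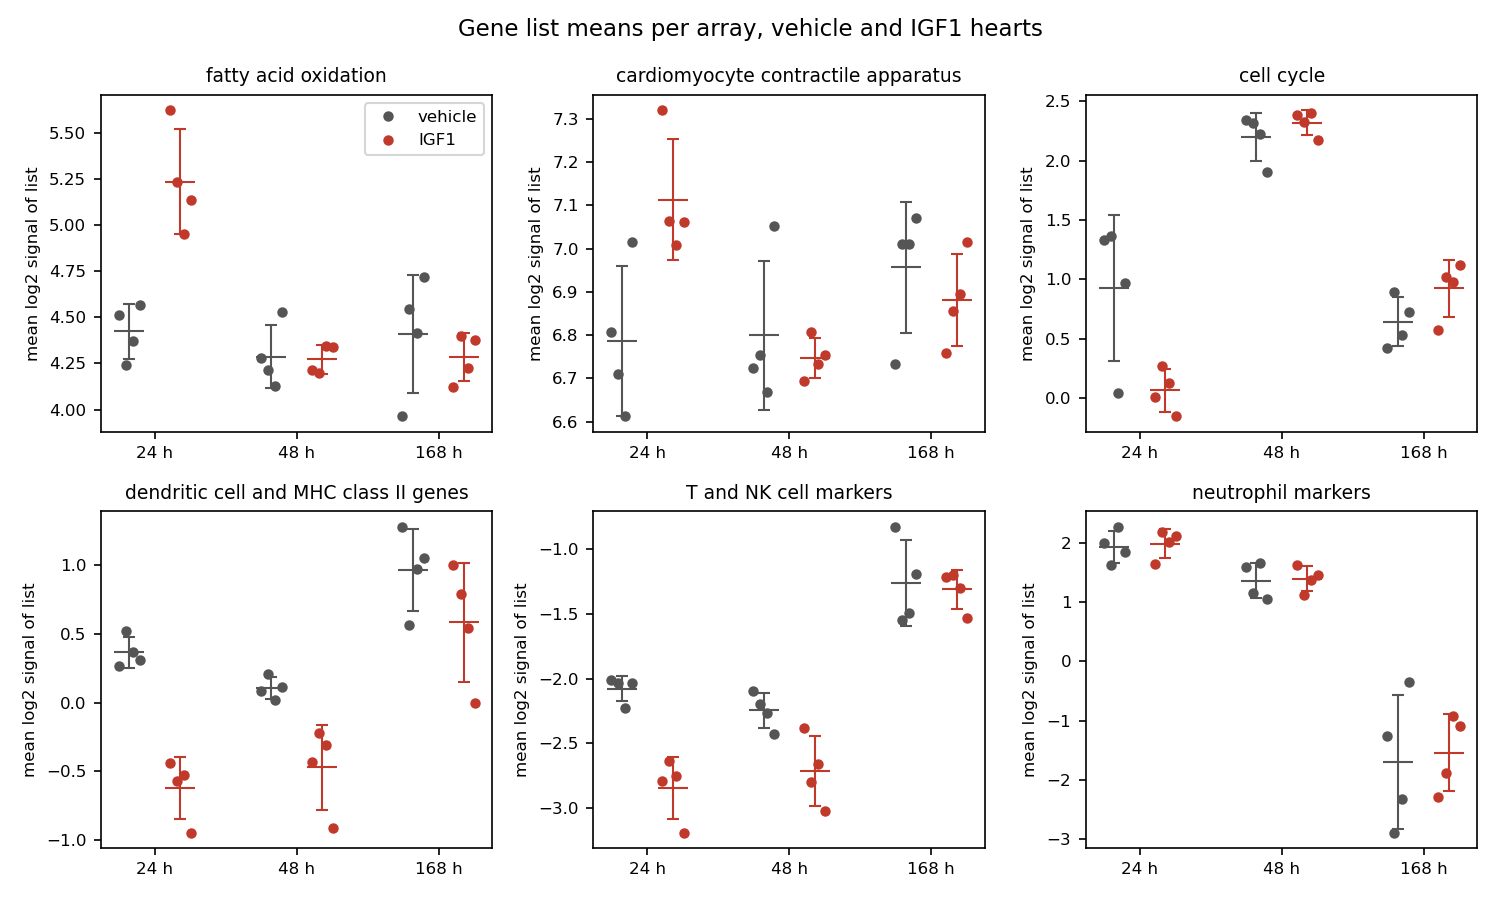
Mean log2 signal of 6 gene lists on each array (points; grey, vehicle; red, IGF1; 4 arrays per group) at 24, 48 and 168 h, with the group mean and SD as bars. The fatty acid oxidation mean stood at 5.24 ± 0.28 with IGF1 and 4.42 ± 0.15 with vehicle at 24 h, and at 4.27 ± 0.08 and 4.29 ± 0.17 at 48 h.

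Proliferation genes were lower as well. Of 26 cell cycle genes, 23 fell and 0 rose, with 25 lower adjusted over the list alone. The median was -0.96 (camera adjusted p = 4.48e-15, adjusted p = 0.305 with estimated correlation). Birc5, which acts in chromosome segregation, was 2.26-fold lower (adjusted p = 0.0045). The mitotic transcription factor Foxm1 was 2.28-fold lower (adjusted p = 0.00608) and the replication helicase gene Mcm6 was 1.51-fold lower (adjusted p = 0.00389). The list mean was lower on 3 of 4 slides, from -1.32 to 0.08. The vehicle arrays themselves were spread widely in this list (0.93 ± 0.62 against 0.06 ± 0.18 with IGF1). Vehicle replicate 3 had a Foxm1 value of -1.80 where the other vehicle arrays had -0.35 to -0.08. In the list of apoptosis regulators 4 of 16 genes fell, 1 rose and 11 did not pass (5 lower and 2 higher adjusted over the list alone). The median was -0.16 (camera adjusted p = 0.0416, adjusted p = 0.548 with estimated correlation). The BH3-only genes Pmaip1 and Bid were 2.23-fold and 1.54-fold lower (adjusted p = 0.000382 and 0.00375), and the death receptor Fas was 1.43-fold higher (adjusted p = 0.00579). Apaf1, which activates caspases, was 1.31-fold lower (adjusted p = 0.0181). Its call was lost without IGF1 replicate 1 (0.0724), with the 24 h arrays alone (0.0629) and with the mean of probes (0.238), with a range of 0.00665 to 0.238. The call of this list was lost with normexp background correction (adjusted p = 0.054). Its mean within slides ran from -0.44 to 0.01.

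Markers of myeloid cells did not move as 1 group at 24 h. Of 19 neutrophil markers, 1 rose and 0 fell (camera adjusted p = 0.999; median 0.01 and mean 0.06 of the fitted differences, while the test pointed down). The member that rose was Lcn2, which binds bacterial iron carriers, 2.80-fold higher (adjusted p = 0.0168). The log2 differences of Ly6g and S100a8 were 0.37 and 0.01 (adjusted p = 0.103 and 0.995). Among 16 inflammatory monocyte markers 5 fell and 2 rose, and the list was not called (median -0.24, adjusted p = 0.0539). The chemokine receptor Ccr2 was 2.09-fold lower (log2 -1.07, SE 0.15, adjusted p = 0.000485). The growth factor receptor Csf1r (log2 -0.59, adjusted p = 0.000979) and Adgre1, which codes for F4/80 (log2 -0.74, adjusted p = 0.0049), were lower too. Ly6c2 was 1.41-fold higher (adjusted p = 0.0148). Sirpb1a and Cd68 were lower as well and Ly6c1 higher (log2 -0.76, -0.66 and 0.47, adjusted p = 0.0223, 0.0415 and 0.0261). Their calls were lost without 4, 8 and 4 of the 8 arrays in turn, and those of Cd68 and Ly6c1 under 3 and 1 other settings (up to 0.077, 0.111 and 0.108 over all alternatives). Of 20 resident and reparative macrophage markers 3 fell and 2 rose (camera adjusted p = 0.535; median 0.00 and mean 0.10, while the test pointed down). The scavenger receptor Stab1 was 1.47-fold and the transcription factor Maf 1.56-fold lower (adjusted p = 0.00248 and 0.0115). Lyve1, Vsig4 and Cd209d had log2 differences of 0.82, 1.23 and -0.70 (adjusted p = 0.0221, 0.0234 and 0.0408). Vsig4 was above background on 1 of 4 vehicle arrays. These genes lost their calls without 3, 3 and 5 arrays in turn and under 0, 2 and 3 other settings (up to 0.0734, 0.147 and 0.151 over all alternatives). Cd28, Csrp3, Sirpb1a, Cd68, Ly6c1, Cd209d and Apaf1 were chosen after their values were seen. Without vehicle replicate 2 the calls of Lcn2 and Ly6c2 were lost (adjusted p = 0.0567 and 0.0593), as was that of Ly6c2 with the 24 h arrays alone (0.0765). Over all alternatives the adjusted p ran from 0.00754 to 0.0567 for Lcn2 and from 0.00907 to 0.0765 for Ly6c2.

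Also called at 24 h, inflammatory cytokines and chemokines had a median of -0.42 over 19 genes (camera adjusted p = 0.00934, adjusted p = 0.536 with estimated correlation). Activated fibroblast markers had -0.28 over 17 (camera adjusted p = 0.00823, adjusted p = 0.548 with estimated correlation). In each 1 gene fell and 0 rose, with 0 adjusted over the list alone. Interferon-stimulated genes had -0.26 over 23, with 1 falling, 0 rising and 1 lower adjusted over the list alone (camera adjusted p = 0.0159, adjusted p = 0.765 with estimated correlation). The interferon-induced chemokine Cxcl10 was 2.34-fold lower (adjusted p = 0.00915). The other members that fell were the chemokine Ccl4 (log2 -1.06, adjusted p = 0.0482) and the fibroblast gene Ltbp2 (log2 -0.62, adjusted p = 0.043). Their calls were lost without 8 and 6 of the 8 arrays in turn and under 2 other settings each (0.0132 to 0.118 and 0.0155 to 0.173 over all alternatives). Il1b had a log2 difference of -1.23 (SE 0.42) and missed the threshold (adjusted p = 0.05, and 0.0195 to 0.143 over the alternatives, 8 of which took it past the threshold). Within slides the cytokine list was lower on 4 of 4 (-0.57 to -0.32), the activated fibroblast list on 4 of 4 (-0.72 to -0.01) and the interferon list on 3 of 4 (-0.58 to 0.16). Of the 24 measured genes named in advance, 3 passed: Ly6c2, Adgre1 and Igf1 itself, whose own transcript was 1.45-fold lower (log2 -0.53, SE 0.16, adjusted p = 0.0296). The other 21 had log2 differences of -1.23 to 0.96 (adjusted p from 0.05 to 0.995), among them the natriuretic peptide Nppa at -0.15, collagen Col1a1 at -0.35 and the IGF1 receptor gene Igf1r at -0.29. The call of Igf1 was lost without vehicle replicate 1 (adjusted p = 0.0909), vehicle replicate 2 (0.0978) or IGF1 replicate 4 (0.0871), with no filter on dim probes (0.0523) and with the 24 h arrays alone (0.102). That of Col1a1 was gained without vehicle replicate 3 (0.0296) and with array weights (0.0431). Over all alternatives the adjusted p of Igf1 ran from 0.00352 to 0.102 and that of Col1a1 from 0.0296 to 0.287.

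Across all genes, 2542 of 15875 (16.0%) passed limma's test at 24 h, 1390 higher and 1152 lower with IGF1, and 340 of them differed more than 2-fold. All IGF1 arrays lay above all vehicle arrays for 1601 genes and below them for 1319, together 18.4% (chance share 2.86%). Among the largest differences, Vwa3a was 5.27-fold higher (log2 2.40, SE 0.41, adjusted p = 0.00146). The lectin Lgals4 was 4.34-fold higher (adjusted p = 0.000641). Ubxn10 and the ferritin receptor Scara5 were 6.80-fold and 4.55-fold higher (adjusted p = 0.00231 and 0.00248), each well above background on 1 of 4 vehicle arrays. Serpina3c, below background on 4 of 4 vehicle arrays, was at least 1.72-fold higher (adjusted p = 0.00476). The eosinophil lectin Siglecf was 3.29-fold lower (adjusted p = 0.00152). Cst7 and Spns3, above background on 2 of 4 vehicle arrays and 0 of 4 IGF1 arrays, were at least 1.77-fold and 1.33-fold lower (adjusted p = 0.0078 and 0.000299). Of all genes 34.6% had 1 sign on 4 of 4 slides (12.5% by chance), and with slide as a block 3436 passed. The count was 1319 without vehicle replicate 2, 1203 without IGF1 replicate 1 and 947 with the 24 h arrays alone. The last also ended the calls of Ogdh, Bnip3, Fbxo32, Mcm6, Birc5 and Foxm1 (adjusted p from 0.0524 to 0.0813). Normexp ended that of Serpina3c (0.102) and the mean of probes that of Foxm1 (0.126).

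At 48 h few single genes passed. Il6 was 5.58-fold lower with IGF1 (log2 -2.48, SE 0.34, adjusted p = 0.00648). It stood at 0.89 ± 0.95 against 3.37 ± 0.15 with vehicle (SD, n = 4). Cd7, found on T and NK cells, was 2.61-fold lower (log2 -1.38, SE 0.20, adjusted p = 0.00648) and above background on 3 of 4 IGF1 arrays. Of 19 cytokine and chemokine genes 1 fell and 0 rose, with 8 lower and 0 higher adjusted over the list alone. The median was -0.47 (camera adjusted p = 1.8e-09, adjusted p = 0.0865 with estimated correlation). Il11 and Osm did not pass, with log2 differences of -2.13 and -1.17 (both adjusted p = 0.209). Lif, below background on 4 of 4 IGF1 arrays, was at least 2.19-fold lower (adjusted p = 0.209). In the dendritic cell and MHC class II list 0 genes passed over all genes and 8 were lower adjusted over the list alone (median -0.64, camera adjusted p = 4.29e-09, adjusted p = 0.203 with estimated correlation). H2-Ab1 differed by -0.78 and Cd74 by -0.70 (adjusted p = 0.343 and 0.419). Of the T and NK cell markers 0 passed and 7 were lower adjusted over the list alone (median -0.41, camera adjusted p = 5.58e-08, adjusted p = 0.12 with estimated correlation). Klrd1 differed by -1.01 (adjusted p = 0.209). Of the B cell markers 0 passed and 1 was lower over the list alone (median -0.25, camera adjusted p = 0.00152, adjusted p = 0.197 with estimated correlation).

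Also called at 48 h was alternative macrophage activation (median -0.37 over 14 genes, camera adjusted p = 0.0128, adjusted p = 0.33 with estimated correlation). Erythrocyte genes were called downward (median -1.30 over 10, camera adjusted p = 0.026, adjusted p = 0.957 with estimated correlation) and smooth muscle and pericyte markers upward (median 0.18 over 10, camera adjusted p = 0.0259, adjusted p = 0.203 with estimated correlation). In each 0 members passed, over all genes and adjusted over the list alone. The fatty acid oxidation and cell cycle lists, called at 24 h, had medians of -0.01 and 0.12 (0.07 and 0.16 with slide as a block, camera adjusted p = 0.979 and 0.0564). On the 2 slides that held both treatments the list means differed by -1.21 and -0.68 for cytokines, -0.63 and -0.48 for class II genes, -0.58 and -0.44 for T and NK cell markers and -0.47 and -0.38 for B cell markers. They differed by -0.45 and -0.28 for alternative activation, -0.67 and -0.56 for erythrocyte genes and 0.10 and 0.25 for smooth muscle markers. With slide as a block their medians were -0.47, -0.68, -0.49, -0.32, -0.34, -1.40 and 0.14. With no filter on dim probes the calls of alternative activation and erythrocyte genes were lost (adjusted p = 0.0769 and 0.104), the latter also with array weights (0.0659). That of smooth muscle markers was lost with the filter on all arrays (0.0842).

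In total 2 genes passed limma's test at 48 h, both lower (1410 had an unadjusted p below 0.05). All IGF1 arrays lay above or below all vehicle arrays for 5.89% of the genes (chance share 2.86%). Among the higher genes with the smallest p, which did not pass, the muscarinic receptor Chrm2 had a log2 difference of 0.58 (adjusted p = 0.211) and the ceramidase Acer2 0.78 (adjusted p = 0.224). Among the lower ones the B cell factor Pax5 had -1.01 (adjusted p = 0.119), the lymphocyte receptor Cd226 -1.46 (adjusted p = 0.199) and the interleukin 10 receptor Il10ra -0.65 (adjusted p = 0.209). The other 23 genes named in advance had log2 differences of -1.46 to 0.56 (adjusted p from 0.285 to 0.978), with Il1b at -1.46, Igf1 at 0.08 and Col1a1 at -0.04. With slide as a fixed block 56 genes passed (2 with a random block), 2 higher and 54 lower, including Pax5, Cd226, Il10ra, Il11 and Osm (adjusted p from 0.0344 to 0.0496). Within slides Il6 differed by -1.99 and -3.12 and Cd7 by -1.22 and -1.60. With the 48 h arrays alone 0 genes passed (Il6 and Cd7 both at 0.326), with the filter on all arrays 1 passed, and without IGF1 replicate 1 there were 4, among them Il11 (0.0103). Osm passed without vehicle replicate 4 (0.0425) and Pax5 with array weights (0.00341). Over all alternatives the adjusted p of Il6 ran from 7.29e-05 to 0.326, that of Cd7 from 0.00418 to 0.326, that of Il11 from 0.0103 to 0.541, that of Osm from 0.0344 to 0.541 and that of Pax5 from 0.00341 to 0.492.

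At 168 h, when the infusion had ended, 0 genes passed limma's test (615 had an unadjusted p below 0.05, smallest adjusted p 0.0778). Spp1, the gene of the matrix protein osteopontin, stood at 5.69 ± 1.65 with IGF1 and 2.85 ± 0.08 with vehicle (SD, n = 4), a log2 difference of 2.84 (SE 0.47, adjusted p = 0.0778). The macrophage elastase Mmp12 differed by 2.31 (SE 0.51, adjusted p = 0.395) and the interleukin 1 receptor antagonist Il1rn by 1.83 (adjusted p = 0.96). Neuropeptide Y (Npy), above background on 3 of 4 IGF1 arrays and 0 of 4 vehicle arrays, was at least 3.59-fold higher (adjusted p = 0.0778). Among the lower genes were the interferon-induced GTPases Gbp4 and Irgm2 at -1.22 and -0.95 (adjusted p = 0.415 and 0.683) and the class II alpha chain H2-Aa at -0.81 (adjusted p = 0.683). All IGF1 arrays lay above or below all vehicle arrays for 2.65% of the genes (chance share 2.86%). All 24 genes named in advance had an adjusted p of 1, with log2 differences of -0.23 to 1.49, among them Chil3 at 1.49 and Igf1 at 0.33.

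By the list test 11 lists were called at 168 h, with 0 members past the threshold over all genes. Exact permutation of their list means, two-sided, gave p of 0.114 to 0.6. Matrix proteases and inhibitors had a median of 0.26 (camera adjusted p = 3.45e-07, adjusted p = 0.213 with estimated correlation), with 2 higher adjusted over the list alone. Cell cycle genes had 0.28 (camera adjusted p = 1.26e-08, adjusted p = 0.578 with estimated correlation). Resident and reparative macrophage markers had a median of 0.31 (camera adjusted p = 0.000156, adjusted p = 0.427 with estimated correlation). Inflammatory monocyte markers and alternative macrophage activation both had 0.28 (camera adjusted p = 0.00129 and 0.00159, 0.484 and 0.427 with estimated correlation). Of the monocyte markers 2 were higher adjusted over the list alone. Extracellular matrix genes and activated fibroblast markers had medians of 0.07 and 0.13 (both camera adjusted p = 0.0347, adjusted p = 0.754 with estimated correlation). Lower were the dendritic cell and MHC class II list at -0.52 (camera adjusted p = 2.39e-07, adjusted p = 0.427 with estimated correlation), with 7 lower adjusted over the list alone, and interferon-stimulated genes at -0.25 (camera adjusted p = 1.41e-06, adjusted p = 0.603 with estimated correlation). FoxO targets had -0.09 and fatty acid oxidation genes -0.14 (camera adjusted p = 0.00432 and 0.00563, 0.495 and 0.754 with estimated correlation). In the other 8 lists 0 members passed adjusted over the list alone.

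On the 2 slides that held both treatments at 168 h, the list means differed by -1.05 and -0.16 for class II genes, -0.31 and -0.24 for interferon genes, 0.24 and 0.40 for cell cycle genes and 0.11 and 0.42 for proteases. They differed by 0.16 and 0.22 for resident macrophage markers and 0.01 and 0.43 for monocyte markers. For alternative activation the values were 0.10 and 0.55, for matrix genes 0.02 and 0.31, for activated fibroblast markers 0.01 and 0.49, for fatty acid oxidation -0.34 and -0.06 and for FoxO targets -0.21 and -0.10. Spp1 differed by 2.63 and 3.49 within slides. Without IGF1 replicate 1, whose removal took the count to 10 genes, Spp1 (adjusted p = 8.65e-05), Npy (0.00255), Mmp12 (0.0101) and Il1rn (0.0115) passed. Array weights gave 8 genes, and normexp and the filter on all arrays 1 each. The adjusted p over all alternatives ran from 8.65e-05 to 1 for Spp1, from 0.00255 to 0.884 for Npy, from 0.0101 to 1 for Mmp12 and from 0.0115 to 1 for Il1rn. With the replicate number as a block in the 168 h arrays alone 0 genes passed and the list of inflammatory monocyte markers was not called (0.0645). Array weights ended the calls of matrix genes and activated fibroblast markers (both 0.0967), and quantile normalization also ended the latter (0.0507).

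**Figure D2:**
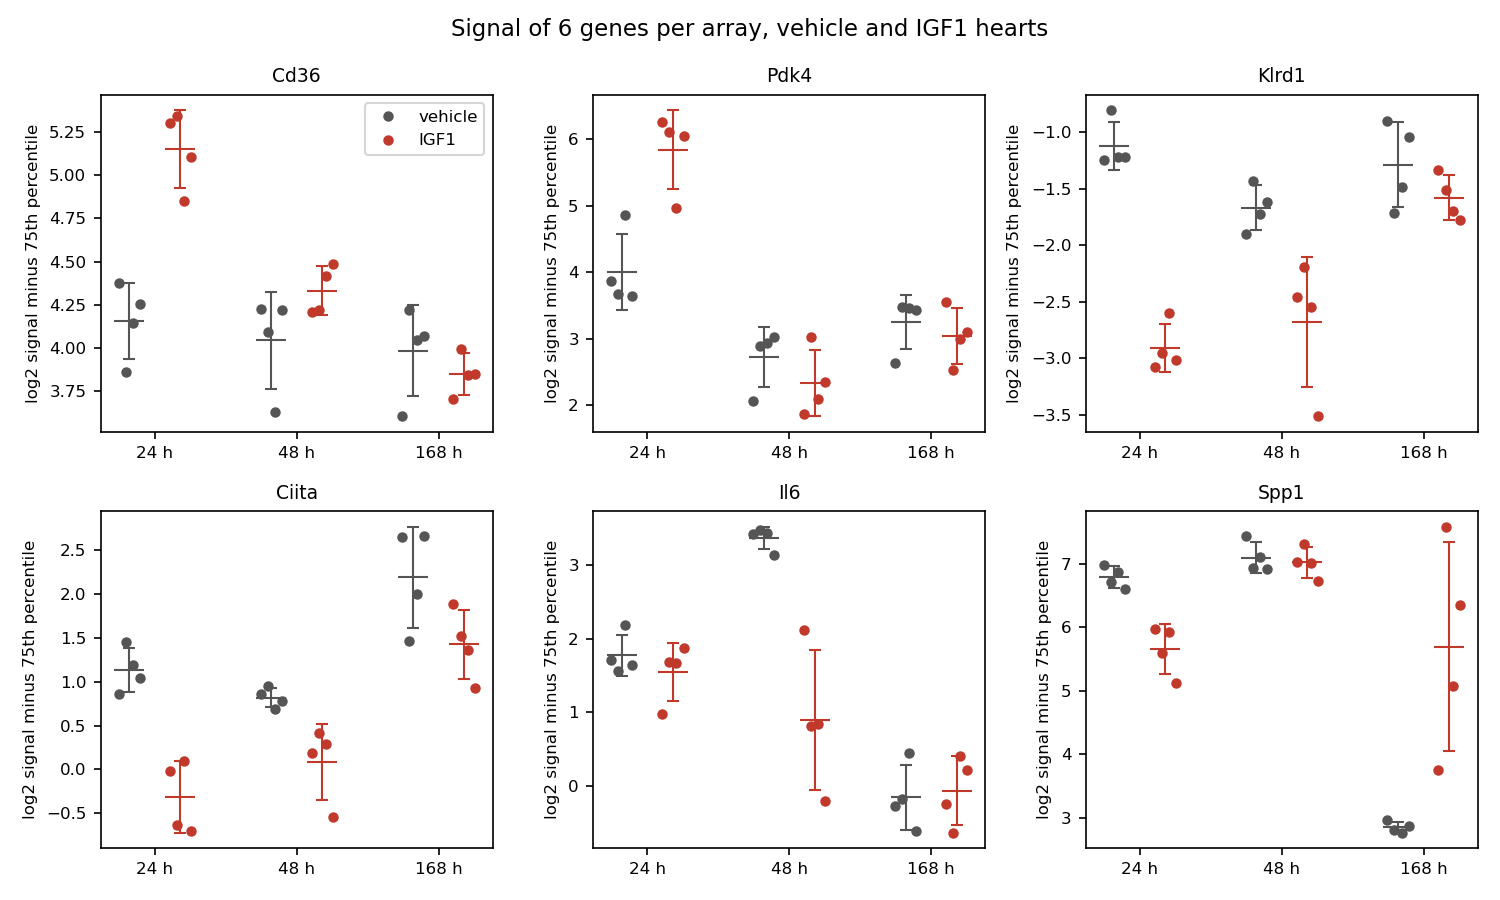
Log2 signal minus the 75th percentile of the array for Cd36, Pdk4, Klrd1, Ciita, Il6 and Spp1 (points, single arrays; grey, vehicle; red, IGF1; 4 arrays per group) at 24, 48 and 168 h, with mean and SD as bars. Pdk4 stood at 5.84 ± 0.59 with IGF1 and 4.01 ± 0.57 with vehicle at 24 h.

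In the mean of the 3 differences, class II and lymphocyte genes were lower with IGF1. At 168 h alone, T and NK cell markers and B cell markers were not called (medians -0.03 and -0.09, camera adjusted p = 0.853 and 0.775), with 1 of 2 slides lower for each. Of 15 dendritic cell and MHC class II genes 8 fell and 0 rose, with 14 lower adjusted over the list alone. The median was -0.72 (camera adjusted p = 2.17e-22, adjusted p = 0.0262 with estimated correlation). The class II chains H2-Ab1, H2-Eb1 and H2-Aa had mean log2 differences of -0.90, -0.87 and -0.84 (SE 0.14, 0.13 and 0.13, each adjusted p = 0.00474). Ciita had -0.98 (adjusted p = 0.00474) and the invariant chain Cd74 -0.84 (adjusted p = 0.00838). Of 13 T and NK cell markers 2 fell and 0 rose, with 10 lower adjusted over the list alone (median -0.46, camera adjusted p = 1.48e-10, adjusted p = 0.0262 with estimated correlation). Klrd1 was 2.04-fold lower (log2 -1.03, SE 0.13, adjusted p = 0.000736). Cd7, outside that list, was 2.01-fold lower (log2 -1.01, SE 0.11, adjusted p = 0.000366). Of 7 B cell markers 1 fell and 0 rose, with 5 lower adjusted over the list alone (median -0.58, camera adjusted p = 2.6e-06, adjusted p = 0.0262 with estimated correlation). Ccr2 was 1.54-fold lower (adjusted p = 0.00434) and the lymphocyte receptor Gpr171 had a difference of -0.75 (adjusted p = 0.006).

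Cytokine genes had a median of -0.30 over the 3 times (0 passed, 7 lower adjusted over the list alone, camera adjusted p = 8.21e-08, adjusted p = 0.057 with estimated correlation). Il6 itself had -0.87 (SE 0.20, adjusted p = 0.0503). Fatty acid oxidation genes had a median of 0.21 (0 passed, 3 higher adjusted over the list alone, camera adjusted p = 2.64e-09, adjusted p = 0.47 with estimated correlation). Of the other lists called, oxidative phosphorylation (0.10) and resident fibroblast markers (0.11) had medians above 0, and cell cycle (-0.16), interferon-stimulated (-0.11), erythrocyte (-0.71) and cardiac stress genes (-0.17) below 0. Their camera adjusted p lay between 0.000267 and 0.0262, adjusted p = 0.767 with estimated correlation for each. In these 0 members passed, and 1 each of the fibroblast, interferon and cardiac stress lists adjusted over the list alone. The calls of cardiac stress genes (0.0724 to 0.122 under 3 alternatives) and resident fibroblast markers (0.0881 with the mean of probes) were not kept throughout. In all 75 genes passed, 9 higher and 66 lower, of which 42 had 1 sign at all 3 times (37 lower, 5 higher). At 24 h 74 were also called with the same sign. Higher genes included the serine protease inhibitors Serpina3m at 0.87 and Serpina1e at 0.78 (SE 0.16 and 0.17, adjusted p = 0.0239 and 0.0448). Others were the endothelial gene Tmem100 at 0.56, Rtn4rl1 at 0.34 and the phospholipid acyltransferase Lpcat3 at 0.26 (adjusted p = 0.0252, 0.0475 and 0.045). None of these 5 calls held throughout. Over the 34 alternatives the adjusted p reached 0.0538, 0.496, 0.063, 0.136 and 0.0935. Serpina3m was lost without vehicle 168 h replicate 1 (0.0502) or IGF1 168 h replicate 3 (0.0538). Lck (-0.46, adjusted p = 0.0341) was also lost under some (up to 0.078). Il6 was gained under 4 other settings (0.0346 to 0.0477) and without IGF1 48 h replicate 1 (0.00802), with a range of 0.00802 to 0.0969. With slide as a fixed block 165 genes passed, with no filter 30 and with the mean of probes 46. Leaving out vehicle replicates in turn gave 38 and 29 (24 h, replicates 2 and 4), 38, 38 and 43 (48 h, 1 to 3) and 17, 129, 43 and 44 (168 h, 1 to 4). Leaving out IGF1 replicates gave 49, 118 and 39 (24 h, 2 to 4), 44 and 23 (48 h, 2 and 4) and 15 and 40 (168 h, 3 and 4).

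Whether the IGF1 effect differed between times was tested by limma's F-test, which 889 of 15875 genes (5.6%) passed. Among the smallest adjusted p was that of Tacc2 (0.00137). Cyth4, Thrsp, Bend5, Cd48 and Cd300c2 (each 0.00172), Cd300ld (0.00184) and Ncapg2 (0.00241) followed. Bend5 was lost with the mean of probes (0.105, with 0.000858 to 0.105 over the alternatives). Cd36 (0.0135), Pdk4 (0.0145), Klrd1 (0.0222), Il6 (0.00963) and Spp1 (0.00789) also passed. By single steps, the IGF1 effect at 48 h differed from that at 24 h for 11 genes (2 higher, 9 lower). That at 168 h differed from that at 48 h for 0 genes (1082 with an unadjusted p below 0.05). The list test called 9 and 8 lists for these steps, 0 of them with an estimated correlation. The difference between 48 h and 24 h had a median of -0.71 in fatty acid oxidation, -0.47 in oxidative phosphorylation, -0.45 in the contractile list, 1.09 in cell cycle and 0.42 in class II genes. With slide as a block 1528 genes passed the F-test, with no filter 406 and with array weights 1953. Without vehicle 24 h replicates 1 and 2 in turn it was 536 and 342, and without IGF1 24 h replicate 1 it was 401. Without vehicle 168 h replicates 1, 2 and 3 in turn it was 1418, 535 and 536, and without IGF1 168 h replicates 2, 3 and 4 it was 535, 516 and 560.

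The change from 24 to 48 h within each treatment shows the course of the infarct tissue. In these comparisons between times, counts adjusted over the list alone were the same unless given. In vehicle hearts, proliferation and matrix genes rose. Of 26 cell cycle genes 19 rose and 0 fell (median 1.49, camera adjusted p = 6.79e-15, adjusted p = 0.298 with estimated correlation). The cyclin Ccnb2 was 7.32-fold higher (log2 2.87, SE 0.30, adjusted p = 5.05e-06) and the anaphase activator Cdc20 4.44-fold higher (adjusted p = 1.41e-05). Of 23 extracellular matrix genes 18 rose and 0 fell (median 0.98, camera adjusted p = 6.79e-15, adjusted p = 0.206 with estimated correlation). Col1a1 was 3.56-fold higher (log2 1.83, SE 0.15, adjusted p = 5.54e-07). Of 17 activated fibroblast markers 10 rose and 0 fell, 11 rising adjusted over the list alone (median 0.66, camera adjusted p = 3.14e-07, adjusted p = 0.298 with estimated correlation). Cthrc1 was 6.13-fold higher (log2 2.62, SE 0.23, adjusted p = 9.74e-07) and the fibroblast activation protein Fap 3.09-fold higher. Resident fibroblast markers rose in 8 of 12, 0 falling (median 0.70, camera adjusted p = 3.06e-06, adjusted p = 0.298 with estimated correlation), 9 adjusted over the list alone. Resident macrophage markers rose in 9 of 20, 1 (Cd209d) falling (median 0.59, camera adjusted p = 0.000161, adjusted p = 0.298 with estimated correlation). The chemokine Ccl8 was 4.13-fold and Stab1 1.92-fold higher. Interferon-stimulated genes had 4 of 23 rising and 0 falling (median 0.44, camera adjusted p = 0.000261, adjusted p = 0.636 with estimated correlation). Cxcl10 rose 2.86-fold and Isg15, Ifit3 and Bst2 by 1.64-fold, 1.68-fold and 1.36-fold (adjusted p = 0.0267, 0.0385 and 0.0403), with up to 0.0848, 0.122 and 0.129 over the alternatives. Il6 rose 3.03-fold (log2 1.60, SE 0.34, adjusted p = 0.00244). The WNT modulator Sfrp2 was 9.59-fold higher (log2 3.26, SE 0.35, adjusted p = 5.43e-06). Ecrg4, below background on 4 of 4 arrays at 24 h, was at least 3.17-fold higher (adjusted p = 1.41e-05).

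Lower in vehicle hearts at 48 h than at 24 h were ribosome biogenesis genes (11 of 15 fell, 0 rose, 13 falling adjusted over the list alone, median -0.46, camera adjusted p = 1.53e-06, adjusted p = 0.298 with estimated correlation). Unfolded protein and heat shock genes fell in 5 of 16, 0 rising (median -0.40, camera adjusted p = 0.00233, adjusted p = 0.536 with estimated correlation). They were the chaperone genes Hspa1a, Hspa1b, Hspb1 and Dnajb9, with Hspa1a 3.17-fold lower (adjusted p = 0.00018), and the stress factor Ddit3 (log2 -0.45, adjusted p = 0.0346, 0.0158 to 0.0909 over the alternatives). Ddit3 and Cd209d (log2 -0.70, adjusted p = 0.0311, 0.0173 to 0.138) were chosen after their values were seen. Endothelial markers fell in 6 of 20, 0 rising (median -0.25, camera adjusted p = 0.00363, adjusted p = 0.536 with estimated correlation), with 7 falling and 1 rising adjusted over the list alone. The stretch-responsive muscle gene Ankrd2 was 6.46-fold lower (log2 -2.69, SE 0.36, adjusted p = 4.26e-05) and the chemokine Ccl17 4.65-fold lower (adjusted p = 0.00236). Pdk4 was 2.44-fold lower (adjusted p = 0.00883). Across all genes 3609 passed limma's test, 1776 higher and 1833 lower at 48 h, 674 of them by more than 2-fold. With slide as a block 4389 passed, and without vehicle 24 h replicate 3, 2317.

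In IGF1 hearts, the same step raised cell cycle genes in 26 of 26 (median 2.62, camera adjusted p = 6.96e-26, adjusted p = 0.147 with estimated correlation). Ccnb2 was 18.8-fold higher (log2 4.23, SE 0.30, adjusted p = 1.51e-08), Ccnb1 17.1-fold and the mitotic kinase Plk1 15.1-fold. Matrix genes rose in 18 of 23, 0 falling (median 1.19, camera adjusted p = 2.92e-13, adjusted p = 0.147 with estimated correlation), 19 adjusted over the list alone, Col1a1 by 4.41-fold. Activated fibroblast markers rose in 13 of 17, 0 falling (median 1.24, camera adjusted p = 2.24e-09, adjusted p = 0.147 with estimated correlation), Cthrc1 by 8.59-fold. Interferon-stimulated genes rose in 17 of 23, 0 falling (median 0.75, camera adjusted p = 3.49e-08, adjusted p = 0.503 with estimated correlation), 19 adjusted over the list alone, Cxcl10 by 5.40-fold. Resident fibroblast markers rose in 6 of 12 (7 adjusted over the list alone) and fell in 1, Gsn (median 0.50, camera adjusted p = 0.00223, adjusted p = 0.503 with estimated correlation). Resident macrophage markers rose in 10 of 20 and fell in 1, Mgl2, or 2 adjusted over the list alone (median 0.56, camera adjusted p = 0.00245, adjusted p = 0.503 with estimated correlation). Gsn and Mgl2, chosen after their values were seen, differed by -0.38 and -0.41 (adjusted p = 0.0496 and 0.0115), with 0.012 to 0.235 and 0.00245 to 0.0498 over the alternatives.

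Fatty acid oxidation genes fell in 21 of 21 in IGF1 hearts from 24 to 48 h (median -0.82, camera adjusted p = 4.9e-09, adjusted p = 0.503 with estimated correlation). Pdk4 was 11.4-fold lower (log2 -3.51, SE 0.33, adjusted p = 1.89e-07). Oxidative phosphorylation genes fell in 20 of 21, 0 rising (median -0.58, camera adjusted p = 3.13e-08, adjusted p = 0.503 with estimated correlation). Contractile genes fell in 12 of 20, 0 rising (median -0.36, camera adjusted p = 0.00223, adjusted p = 0.504 with estimated correlation). FoxO targets fell in 11 of 22, while 1, the stress-induced Sesn3, rose 1.48-fold (list median -0.26, camera adjusted p = 0.0159, adjusted p = 0.503 with estimated correlation). Endothelial markers fell in 10 of 20 (11 adjusted over the list alone), while 1, the apelin receptor Aplnr, rose 2.14-fold (list median -0.28, camera adjusted p = 0.0125, adjusted p = 0.504 with estimated correlation). Unfolded protein genes fell in 7 of 16 (10 adjusted over the list alone) and ribosome biogenesis genes in 7 of 15, 0 rising in either (medians -0.46 and -0.23, camera adjusted p = 0.0101 and 0.0159, adjusted p = 0.504 and 0.556 with estimated correlation). Matrix proteases had 8 rising (9 adjusted over the list alone) and 3 falling (median 0.28, camera adjusted p = 0.0359, adjusted p = 0.504 with estimated correlation). The 3, chosen after their values were seen, were Timp4, Mmp8 and Adamts1 (log2 -2.20, -0.98 and -0.52, adjusted p = 0.00277, 0.0396 and 0.0212, up to 0.0181, 0.146 and 0.0946 over the alternatives). In all 5964 genes passed, 2583 higher and 3381 lower, 991 by more than 2-fold (5520 with slide as a block). Of these 2421 were called with the same sign in vehicle hearts and 9 with the opposite sign. Quantile normalization ended the calls of the contractile and protease lists (both 0.0501), slide as a block and the 2 groups alone that of matrix proteases and inhibitors (0.0637 and 0.053) and array weights that of FoxO targets (0.0762).

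From 48 to 168 h, acute inflammation genes gave way to matrix genes in both treatments. In vehicle hearts neutrophil markers fell in 15 of 19, 0 rising (median -2.56, camera adjusted p = 2.12e-05, adjusted p = 0.219 with estimated correlation). The calprotectin genes S100a8 and S100a9 were 68.0-fold and 60.9-fold lower (adjusted p = 1.2e-06 and 5.45e-06). Cytokine genes fell in 16 of 19, 0 rising (median -2.61, camera adjusted p = 1.22e-07, adjusted p = 0.176 with estimated correlation). The monocyte chemokines Ccl7 and Ccl2 were 31.6-fold and 23.7-fold lower and the neutrophil chemokine Cxcl1 15.0-fold lower (adjusted p = 2.36e-10, 5.33e-10 and 5.74e-10). Alternative activation genes fell in 10 of 14, 0 rising (median -1.28, camera adjusted p = 0.000714, adjusted p = 0.176 with estimated correlation), the chitinase-like Chil3 by 89.1-fold (log2 -6.48, SE 0.71, adjusted p = 2.67e-07). Cell cycle genes fell in 26 of 26 (median -1.53, camera adjusted p = 4.76e-11, adjusted p = 0.219 with estimated correlation), Mcm5 by 4.04-fold. Ribosome biogenesis genes fell in 15 of 15 (median -0.98, camera adjusted p = 3.22e-08, adjusted p = 0.176 with estimated correlation), Myc by 3.93-fold. Oxidative stress genes fell in 11 and rose in 2 of 16, Sod3 and catalase, Cat (median -0.49, camera adjusted p = 0.00181, adjusted p = 0.176 with estimated correlation). Unfolded protein genes fell in 11 and rose in 1 of 16, Ddit3 (median -0.72, camera adjusted p = 0.00437, adjusted p = 0.426 with estimated correlation). Sod3, Cat and Ddit3, chosen after their values were seen, rose by 0.52, 0.55 and 0.55 on the log2 scale (adjusted p = 0.00756, 0.0025 and 0.00368). Slide as a block ended the calls of Cat and Ddit3 (0.0543 and 0.0827, with 0.000365 to 0.0543 and 0.0011 to 0.0827 over the alternatives).

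Matrix genes rose in 20 of 23 in vehicle hearts from 48 to 168 h (median 1.16, camera adjusted p = 2.45e-10, adjusted p = 0.176 with estimated correlation). Elastin (Eln) was 38.4-fold higher (log2 5.26, SE 0.32, adjusted p = 2.59e-10). Comp was 58.4-fold higher (log2 5.87, SE 0.45, adjusted p = 3.25e-09) and Fmod, which binds collagen fibrils, 106.89-fold higher (above background on 3 of 4 arrays at 48 h). The 1 matrix gene that fell was tenascin C (Tnc), 2.19-fold lower (adjusted p = 6e-04). Activated fibroblast markers rose in 11 (12 adjusted over the list alone) and fell in 2 of 17 (median 1.30, camera adjusted p = 2.12e-05, adjusted p = 0.195 with estimated correlation), the 2 being Tnc and the protease inhibitor Timp1, 2.71-fold lower (adjusted p = 7.28e-07). Resident fibroblast markers rose in 11 of 12, 0 falling (median 1.29, camera adjusted p = 6.7e-06, adjusted p = 0.186 with estimated correlation), Lum by 4.28-fold. T and NK cell markers rose in 9 of 13, 0 falling (median 0.95, camera adjusted p = 0.00181, adjusted p = 0.226 with estimated correlation), Nkg7 by 4.75-fold. Class II genes rose in 11 of 15 (median 0.78, camera adjusted p = 0.00181, adjusted p = 0.435 with estimated correlation), H2-Aa by 3.56-fold, while the dendritic cell integrin Itgax fell 1.92-fold (adjusted p = 0.00954). Interferon-stimulated genes rose in 18 of 23 (19 adjusted over the list alone), 0 falling (median 0.91, camera adjusted p = 1.51e-05, adjusted p = 0.426 with estimated correlation), the chemokine Cxcl9 by 10.2-fold. FoxO targets rose in 13 of 22 (median 0.51, camera adjusted p = 0.00107, adjusted p = 0.195 with estimated correlation). Genes of the IGF axis rose in 7 of 15, 1 (Igf1r) falling (median 0.32, camera adjusted p = 0.0111, adjusted p = 0.195 with estimated correlation), with Igf1 itself 2.06-fold higher (adjusted p = 1.65e-05). Smooth muscle markers rose in 4 of 10 (median 0.34, camera adjusted p = 0.0311, adjusted p = 0.195 with estimated correlation). Of 6 genes chosen as atrial, 4 rose (median 1.24, camera adjusted p = 0.00437, adjusted p = 0.186 with estimated correlation), among them the secreted factor Dkk3 by 19.7-fold. In all 8439 genes passed, 3976 higher and 4463 lower at 168 h, 2103 by more than 2-fold (6847 with slide as a block). That block ended the call of smooth muscle and pericyte markers (0.0551), as the random block did (0.0812). Igf1r had a difference of -0.54 (adjusted p = 0.00858, and 0.593 with the mean of probes, with 0.00376 to 0.593 over the alternatives). Tnc, Timp1, Itgax and Igf1r were chosen after their values were seen.

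In IGF1 hearts 7741 genes passed for the same step, 3584 higher and 4157 lower, 1758 by more than 2-fold (5639 with slide as a block). In vehicle hearts 6520 were called with the same sign and 7 with the opposite sign. S100a9 was 67.1-fold and S100a8 65.6-fold lower (adjusted p = 5.1e-06 and 1.76e-06), Ccl7 20.4-fold, Ccl2 16.2-fold and Chil3 46.7-fold lower. Neutrophil markers fell in 11 and rose in 1 of 19, Elane (median -2.64, camera adjusted p = 7.37e-05, adjusted p = 0.289 with estimated correlation). Cytokine genes fell in 14 of 19, or 15 adjusted over the list alone (median -1.35, camera adjusted p = 3.9e-05, adjusted p = 0.137 with estimated correlation). Cell cycle genes fell in 25 of 26 (median -1.38, camera adjusted p = 2.9e-11, adjusted p = 0.279 with estimated correlation) and ribosome biogenesis genes in 15 of 15 (median -0.99, camera adjusted p = 1.73e-09, adjusted p = 0.129 with estimated correlation). Matrix genes rose in 22 of 23, 1 (Tnc) falling (median 1.39, camera adjusted p = 2.25e-13, adjusted p = 0.129 with estimated correlation), Comp by 52.4-fold, Eln by 27.2-fold and Fmod by 79.6-fold. Activated fibroblast markers rose in 13 and fell in 2 of 17 (median 1.5, camera adjusted p = 1.56e-06, adjusted p = 0.154 with estimated correlation), Timp1, chosen after its value was seen, falling 2.12-fold. Resident fibroblast markers rose in 10 of 12 (median 1.21, camera adjusted p = 1.28e-05, adjusted p = 0.165 with estimated correlation). T and NK cell markers rose in 12 of 13 (median 1.34, camera adjusted p = 2.42e-06, adjusted p = 0.129 with estimated correlation). Class II genes rose in 11 of 15 (median 1.14, camera adjusted p = 0.000103, adjusted p = 0.325 with estimated correlation), H2-Aa by 3.08-fold.

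Also higher at 168 h in IGF1 hearts were genes of the IGF axis, with 10 of 15 rising and 2, Igf1r and Igfbp3, falling (median 0.54, camera adjusted p = 0.00205, adjusted p = 0.129 with estimated correlation) and Igf1 2.45-fold higher (adjusted p = 1.59e-06). Interferon-stimulated genes rose in 10 of 23, 0 falling (median 0.45, camera adjusted p = 0.00272, adjusted p = 0.606 with estimated correlation). FoxO targets rose in 10 (12 adjusted over the list alone) and fell in 1 of 22, Cited2 (median 0.38, camera adjusted p = 0.00424, adjusted p = 0.289 with estimated correlation). Atrial genes rose in 6 of 6 (median 0.94, camera adjusted p = 0.00171, adjusted p = 0.129 with estimated correlation). Oxidative stress genes fell in 10 (11 adjusted over the list alone) and rose in 1 of 16, Sod3 (median -0.38, camera adjusted p = 0.00178, adjusted p = 0.129 with estimated correlation). Unfolded protein genes fell in 10 and rose in 1 of 16, Ddit3 (median -0.51, camera adjusted p = 0.0072, adjusted p = 0.447 with estimated correlation). Alternative activation genes fell in 7 of 14, or 8 adjusted over the list alone (median -0.99, camera adjusted p = 0.0311, adjusted p = 0.325 with estimated correlation) and glycolysis genes in 8 of 16 (median -0.28, camera adjusted p = 0.0311, adjusted p = 0.383 with estimated correlation). The glycolysis call was lost under 4 alternatives (0.0592 to 0.0816), and slide as a fixed or random block ended that of alternative macrophage activation (0.195 and 0.0713). Single members moving against their lists, chosen after their values were seen, were Tnc at -0.86, Elane at 0.56, Igf1r at -0.76, Igfbp3 at -0.65, Cited2 at -0.34, Sod3 at 0.85 and Ddit3 at 0.56. Their adjusted p lay between 0.00012 and 0.0163 and reached 0.206, 0.209, 0.0836, 0.133, 0.0749, 0.00262 and 0.152 over the alternatives.

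**Figure D3:**
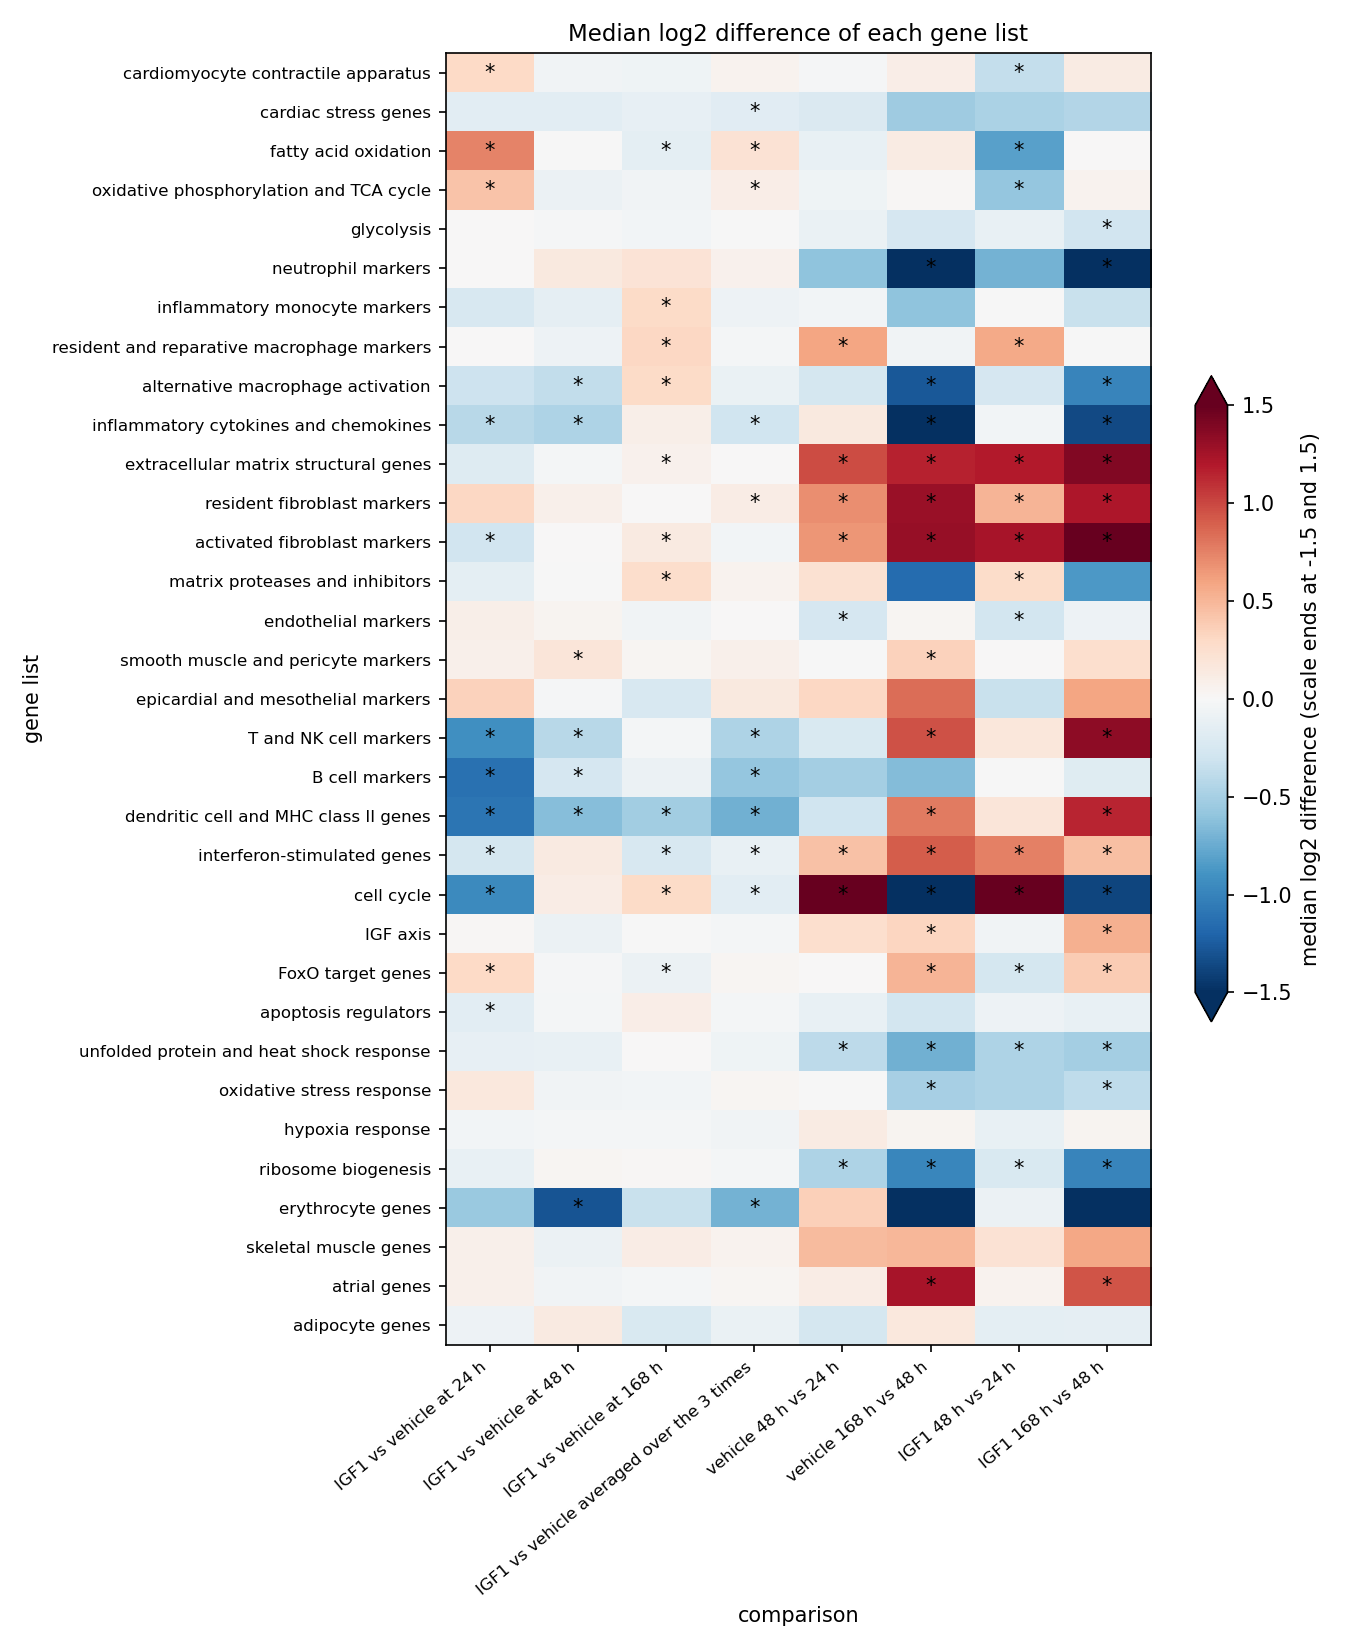
Median log2 difference of 33 gene lists in 8 comparisons (colour, from -1.5 to 1.5); an asterisk marks a camera adjusted p below 0.05 with the preset correlation. With an estimated correlation 3 of these calls hold, those of class II genes, T and NK cell markers and B cell markers in the mean over the 3 times.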

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

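The explanation tests here were chosen after the results were seen, and the splits of the arrays before. The pattern at 24 h was higher fatty acid oxidation genes together with lower lymphocyte and MHC class II genes in IGF1 hearts. More muscle in the excised piece would raise metabolic and contractile genes alike. Yet the fatty acid oxidation list rose by 0.486 more than the contractile list (exact permutation test, two-sided, p = 0.0286, n = 4 per group). Oxidative phosphorylation genes rose by 0.424 and contractile genes by 0.327, so more muscle stays open for the former. Fewer white cells of every kind would lower neutrophil and class II genes alike, yet the gap between these lists was larger with IGF1 than with vehicle by 1.039 (same exact permutation test, p = 0.0286). Of the 35 splits of the 8 arrays, only the real one gave as many genes as the 2542 called (highest other 152). Chance can be excluded for that count. But 8 splits gave as many lists as the 12 called (up to 15), so it cannot for lists. A change in muscle metabolism and fewer lymphocytes or antigen-presenting cells with IGF1 may account for it, and loss of single white cell types, lower expression per cell and a different excised region remain open.

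Lower class II genes in the mean over the 3 times form a related pattern. Averaged over the times, the gap between neutrophil and class II lists was larger with IGF1 by 0.729 (permutation test within times, two-sided, p = 0.0123, 100000 resamples), against fewer white cells of every kind. The class II median was -0.73 with slide as a fixed block (-0.72 without). In 2 of 100 splits as many genes passed as the 75 called, with 124 as the highest other. The count was 15 without IGF1 168 h replicate 3. In 30 of 100 splits as many lists passed as the 11 called, with up to 15. Chance is excluded for neither count. Fewer antigen-presenting cells or lower class II expression with IGF1 could both give this and were not told apart here.

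For the other comparisons, the real split alone gave as many genes, so that chance can be excluded, at 48 h (2, highest other 1; 1 of 35), for vehicle hearts from 24 to 48 h (3609 and 26) and from 48 to 168 h (8439 and 1421), for IGF1 hearts (5964 and 66, 7741 and 0) and for the F-test (889 and 872, but 342 without vehicle 24 h replicate 2; 1 of 100). For the number of lists chance cannot be excluded: 19 of 35 splits at 48 h gave as many as the 7 called (up to 13), 12 at 168 h as the 11 (up to 16), 11 and 9 in vehicle hearts as the 9 and 17 (up to 16 and 21), and 3 and 8 in IGF1 hearts as the 14 and 17 (up to 14 and 20). At 168 h all 35 splits reach the 0 genes called, so their number decides nothing there; the highest other was 32. Of the 8 splits there that part all 4 same-numbered pairs, the highest other called 3. The split that follows the scan day called 0 genes in each comparison where it could be drawn.

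A value far from the other 3 of its group was found in 46 of 910 groups tested (5.05%), and chance alone gives about 1 in 20. In the vehicle 24 h group these were Klrd1 at -0.80 and Vwa3a at -3.83 on replicate 2 and Csf1r at 5.45 on replicate 4. On replicate 3 these were Apaf1 at -1.21, Col3a1 at 4.94, Foxm1 at -1.80, Ncapg2 at -0.54, Ptn at -4.22 and Serpina3m at -1.82. T and NK cell markers were at -2.22 there. In the IGF1 24 h group these were Pdk4 at 4.96 on replicate 3 and alternative macrophage activation at 1.52 on replicate 2. On replicate 4 these were Cd68 at 3.57, Cd74 at 2.77 and Maf at 1.23. On replicate 1 these were Cat at 3.73, Hadhb at 7.72, Igf1r at 2.04, Myoz2 at 6.80 and Ogdh at 7.45. Oxidative phosphorylation and TCA cycle were at 7.69 there. In the vehicle 48 h group these were Pdk4 at 2.06 and Sod3 at 4.88 on replicate 1 and Retnla at -5.25 on replicate 2. On replicate 3 these were H2-Aa at 1.07, Il10ra at 1.5 and Phka2 at 1.76. On replicate 4 these were Adgre1 at 3.30, Fmod at -4.43, Hamp at -3.75, Stab1 at 4.69 and apoptosis regulators at 0.87. In the IGF1 48 h group these were Bend5 at -0.73 on replicate 1, Cdc20 at 2.96 on replicate 4, Chrm2 at 1.84 on replicate 4, Hba-a1 at 8.43 on replicate 1, Mgl2 at 3.88 on replicate 1, Tnf at -0.22 on replicate 2 and epicardial and mesothelial markers at -1.21 on replicate 3. In the vehicle 168 h group these were Col1a1 at 7.81 on replicate 4, Pdk4 at 2.63 on replicate 1, Postn at 6.62 on replicate 4 and glycolysis at 5.19 on replicate 3. In the IGF1 168 h group these were Gzma at 0.81 on replicate 4, Lum at 6.25 on replicate 4 and IGF axis at 1.78 on replicate 1.

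Named genes whose IGF1 effect differed between times by limma's F-test had these adjusted p-values: Tacc2 (0.00137), Bend5, Cd300c2, Cd48, Cyth4 and Thrsp (0.00172), Cd300ld (0.00184), Ncapg2 (0.00241), Spns3 (0.00257), Csf1r (0.00444), Stab1 (0.00734), Spp1 (0.00789), Bach2os, Hmox1 and Lgals4 (0.00796), Il6 (0.00963), Pmaip1 (0.00982), Fcrlb (0.0104), Il10ra (0.0105) and Mlycd (0.0132). Larger values were those of Cpt1b (0.0134), Cd36 (0.0135), Mcm6 (0.0137), Pdk4 and Ubxn10 (0.0145), Cd7 (0.0152), Siglecf (0.0177), Gstm1 (0.0184), Ctss (0.0185), Adgre1 (0.0186), Acot2, E2f1 and Osm (0.019), Mmp14 and Vwa3a (0.0216), Myoz2 (0.0219), Atp2a2, Bnip3 and Klrd1 (0.0222) and Fbxo32 (0.0259). Nearest to the threshold were Birc5 (0.0275), Gbp4 (0.0286), Cd68 (0.0288), Pax5 (0.029), Nqo1 (0.031), Apaf1 and Ccr2 (0.0337), Bend7 (0.0338), Ms4a1 (0.034), Npy (0.038), Foxm1 (0.0386), Acer2, Mmp12, Ogdh and Scara5 (0.0411), Bid and Serpina3m (0.0429), Mcm5 (0.049) and Ly6c2 (0.0495). The median change of the IGF1 effect from 24 to 48 h among lists past the camera threshold was -0.45 for cardiomyocyte contractile apparatus, -0.71 for fatty acid oxidation, -0.47 for oxidative phosphorylation and TCA cycle, 0.32 for activated fibroblast markers, 0.42 for dendritic cell and MHC class II genes, 0.35 for interferon-stimulated genes, 1.09 for cell cycle, -0.24 for FoxO target genes and -0.24 for oxidative stress response. From 48 to 168 h it was 0.59 for inflammatory monocyte markers, 0.38 for resident and reparative macrophage markers, 0.49 for alternative macrophage activation, 0.63 for inflammatory cytokines and chemokines, 0.26 for matrix proteases and inhibitors, 0.44 for T and NK cell markers, 0.36 for B cell markers and -0.41 for interferon-stimulated genes, and 0 of these held with an estimated correlation. Among probes without a gene symbol, which entered no comparison of genes, 163 of 11042 passed at 24 h (90 higher, 73 lower), and 0 at 48 h and 168 h.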

How the results depend on the processing

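The fit with only the 168 h arrays and the replicate number as a block was chosen after seeing the data, and all other alternatives before. No called gene or list turned its direction under an alternative, while some differences near 0 that were not called changed sign. For single named genes, 3817 of the values under other settings kept their side of the threshold, 88 lost it and 34 gained it, and with arrays left out in turn 3568 kept, 194 lost and 14 gained it. For lists 1055 kept and 121 lost their call.

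The count at 24 h became 947 with only the groups compared. At 48 h it was 1 with the filter on all arrays, 56 with slide as a fixed block and 0 with only the groups compared. At 168 h it was 1 with normexp, 1 with the filter on all arrays and 8 with array weights. The count averaged over the times was 30 with no filter, 46 with the mean of probes, 165 and 172 with slide as a fixed and a random block and 114 with array weights, and the F-test gave 406 with no filter, 1528 and 1535 with slide as a fixed and a random block and 1953 with array weights. With an estimated correlation 3 lists were called in the mean over times and 0 in the other 7 comparisons. Fewer arrays enter the fit with only the groups compared; for the others the cause was not tested. With quantile normalization the larger direction turned: 48.6% of called genes were higher at 24 h, 50.8% in either treatment from 24 to 48 h and 53.0 and 52.1% in vehicle and IGF1 hearts from 48 to 168 h.

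With arrays left out in turn the counts ran from 1203 to 2508 at 24 h, 2 to 4 at 48 h, 0 to 10 at 168 h, 15 to 129 in the mean over times and 342 to 1418 in the F-test. In vehicle hearts they ran from 2317 to 3391 for 24 to 48 h and 7712 to 8467 for 48 to 168 h, and in IGF1 hearts from 4968 to 5778 and 6883 to 7376.

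With the replicate number as a block over all arrays, the counts were 2923, 2 and 0 at 24, 48 and 168 h, 105 in the mean over times, 1167 in the F-test, 4076 and 8804 in vehicle hearts and 6443 and 8187 in IGF1 hearts, each within 1.5 times the count without it. With the 168 h arrays alone and that block, 0 genes and 12 lists (6 higher, 6 lower) passed. Outside the 168 h comparison of IGF1 with vehicle the numbers are not taken as pairs: same-numbered arrays correlated with r of -0.05 to 0.134 at 24 h, -0.005 to 0.112 at 48 h, 0.053 to 0.382 and -0.043 to 0.201 in vehicle hearts and -0.066 to 0.144 and -0.076 to 0.05 in IGF1 hearts, with 1, 3, 4, 2, 1 and 1 of 4 arrays closest to their own number. Signal limits the low end: genes not above background on a whole group have bounds only.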

Other observations

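The course test here was chosen after the result was seen. Antioxidant genes moved in both directions at 24 h: of 16 oxidative stress genes 4 rose with IGF1, 1 fell and 11 did not pass, with 7 higher and 2 lower adjusted over the list alone, and the list was not called (median 0.16, camera adjusted p = 0.108). Nqo1, a quinone reductase, was 2.07-fold higher and the glutathione transferase Gstm1 1.59-fold higher (adjusted p = 0.00321 and 0.00268), whereas heme oxygenase Hmox1 was 1.70-fold lower (adjusted p = 0.00811). The superoxide dismutase Sod1, chosen after its value was seen, was 1.19-fold higher (adjusted p = 0.0157), a call lost without vehicle replicate 2 (0.0501) or IGF1 replicate 1 (0.0683) and with the 24 h arrays alone (0.167; 0.00699 to 0.167 over the alternatives), which also ended that of Gstm1 (0.0501; 0.0011 to 0.0501).

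Resident fibroblast markers and matrix proteases were not called at 24 h (medians 0.31 and -0.15, camera adjusted p = 0.0948 and 0.374). Of the 12 fibroblast markers 3 rose and 0 fell: Smoc2, Dpep1 and Gsn were 1.45-fold, 1.60-fold and 1.43-fold higher (adjusted p = 0.0101, 0.0197 and 0.0235), and all 3 calls were lost with the 24 h arrays alone (0.0826, 0.0923 and 0.131). Those of Dpep1 and Gsn were also lost without vehicle replicate 2 (0.0624 and 0.0896), vehicle replicate 3 (0.0582 and 0.074), IGF1 replicate 1 (0.0649 and 0.105) or IGF1 replicate 2 (0.0671 and 0.0545), with ranges of 0.00179 to 0.0826 for Smoc2, 0.00559 to 0.0923 for Dpep1 and 0.00789 to 0.131 for Gsn. Of the 21 proteases and inhibitors 1 rose and 2 fell. The inhibitor Timp4 was 3.74-fold higher (adjusted p = 0.0197; lost under 4 alternatives, among them without vehicle replicate 2 at 0.0794 and IGF1 replicate 2 at 0.0542; 0.0107 to 0.0794), the lysosomal cathepsin gene Ctss 1.79-fold lower (adjusted p = 0.00524) and the membrane protease Mmp14 1.40-fold lower (adjusted p = 0.0139; 0.0554 without IGF1 replicate 1; 0.00696 to 0.0554).

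A hypothesis was that IGF1 hearts at 24 h lie earlier on the course that vehicle hearts follow from 24 to 48 h. Both differences share the vehicle 24 h arrays, and across 15851 genes, which are not independent replicates, their correlation was 0.041 (covariance 0.0073). Simulated unchanged groups gave 0.499 (0.0244), no reference as 3609 genes changed in vehicle hearts. With the vehicle 24 h arrays halved in 6 ways the mean correlation was -0.074 (from -0.199 to 0.073), which does not decide the question. For fatty acid oxidation genes the tables argue against it: in vehicle hearts the list fell by 0.137 (SE 0.113) from 24 to 48 h, where IGF1 and vehicle differed by 0.813 at 24 h. An earlier stage stays open for these genes and for others, such as those of the cell cycle.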
